A study of Mus musculus with 6 samples.

How the data were processed

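Islets were taken from male C57BL6 mice aged 8 weeks, kept on chow under 12 h of light and 12 h of dark, at 6 zeitgeber times (ZT) spaced 4 h apart, with lights on at ZT0 and off at ZT12. Per the labels, RNA of 3 to 5 mice was pooled for each time point, labelled with Cy3 and hybridised to 1 Agilent array per time point. The number of mice in each pool was given only as that range. The arrays were read in 3 scans on 2 dates 6 days apart. The ZT8, ZT12, ZT16 and ZT20 arrays shared a slide and a scan, at positions 1, 2, 3 and 4 in that order. The ZT4 array was scanned on the same date, and the ZT0 array was scanned on the later date.

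Per the file headers, Agilent Feature Extraction 11.0.1.1 produced the scanner files, in which the processed signal was a linear intensity, background-subtracted and detrended, with a positive floor on each array and no normalization between arrays. The deposited files also held median spot and local background intensity, and other columns with flags of 0 or 1 for spots well above background, saturated spots and outlier spots. They held no mean spot signal and no gene name. The authors' value table held log2 values for 30170 probes. Its columns had medians of 8.62 to 8.63 and the same maximum of 18.4, and each correlated across probes with the log2 processed signal of its own array at Pearson's r of 0.9987 to 0.9998, so the scale was log2, the columns shared a distribution as after quantile normalization, and genes were not centred. The steps that the authors took to make those values were not stated.

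Control spots were removed and the spots of a probe were averaged, which left 39429 probes; 399 of these had 10 spots. Values were log2 of the processed signal minus the 75th percentile of all probes on the array. Probes took gene symbols through their accession, without versions, from RefSeq names of GRCm38.p6, used for names only. It matched 27234 probes (69.1%); the other 12195 kept the name in the files. A probe was tested when it was well above background on at least 3 of the 6 arrays and not flagged as an outlier on all of its spots on any array. The outlier condition removed 1415 probes, 1377 of them because of the ZT0 array. This left 28821 probes. The probe with the highest mean was used for each gene, giving 24147 genes, 16824 with a symbol. Among core clock genes with a probe not used, Dbp peaked at ZT6.03 on the probe used and ZT6.96 on the other, whereas Csnk1d gave ZT21.2 and ZT11.9. No coordinates were used.

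A cosine of 24 h period was fitted to each gene with limma 3.58.1 in R 4.3.3 (intercept, cosine and sine, 3 residual degrees of freedom) and its 2 cosine terms were tested with the moderated F test. Benjamini-Hochberg adjustment ran over all genes tested, with a threshold of 0.05, and separately over each gene list. Amplitudes are given as the fitted peak minus trough in log2 units with the standard error (SE), and the fitted time of the peak as the acrophase. For each of 25 gene lists the mean of its gene-centred values was fitted in the same way, and its R-squared was compared with those of all 720 orders of the 6 arrays in an exact permutation test. This test cannot give a p below 0.0167, because rotation and reversal leave 60 distinct circular orders. With 1 array per time point no test between time points was made. In its place, the median deviation of a list from each gene's mean over the 6 arrays was ranked among 10000 random lists matched on expression in 50 bins. Genes well above background on all 6 arrays were counted as standing apart on an array when they were at least 2-fold from the median of the other 5. Where a spot was not well above background, ranges used the higher of its own value and the lowest value among detected probes on that array. Such differences are approximate.

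The 25 lists, the tests and the first set of alternatives were fixed before the data were examined. The lists held the core clock and its activators and repressor-phase genes; glucocorticoid, heat shock, immediate early and inflammatory genes; islet hormones, islet transcription factors, glucose sensing and exocytosis genes; respiratory chain, antioxidant, unfolded protein response, sterol synthesis and cell cycle genes; markers of acinar, duct, endothelial, macrophage, lymphocyte, stromal, red blood and adipocyte cells; and reference genes. The activator and repressor-phase lists were made of core clock genes. A further 4 lists (hepatocyte, lymphoid, intestinal epithelium and smooth muscle genes) were written after the data were examined. The genes named were those with the largest fitted amplitudes that passed the test, 10 with a peak in the light phase and 10 in the dark phase, filled by smallest unadjusted p where fewer passed; the measured core clock genes; up to 4 members of each other list that passed over the list, or otherwise the 2 of highest mean signal; and for each array the 2 genes furthest above and the 2 furthest below the median of the other arrays. Some genes that this rule selects are left out of the text.

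Alternatives changed 1 choice at a time, except that normexp changed the signal column and the background correction together and, with quantile, the scaling too. They were quantile normalization; normexp background correction with an offset of 50, followed by quantile or 75th percentile scaling; the median of detected probes; the authors' values; stricter and no filters on dim probes; the mean of a gene's probes and every probe; trended robust shrinkage and no shrinkage; an exact permutation test per gene; an added 12 h harmonic; periods of 20 h and 28 h; scan as a covariate; a threshold of 0.10; and each array left out. Normexp used the median spot signal, since the mean was not in the files. Chosen after the data were seen were the lymphocyte mean, the islet hormone mean and the scan date as covariates, leaving out the ZT4 and ZT12 arrays together, and keeping outlier spots.

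The fit was tested on simulated arrays with the means of the 24147 genes and residuals drawn from the fitted prior. With no changed gene it called 0 genes and gave an unadjusted p under 0.05 to 5.18% of them. With 200 changed genes it called 0 at peak-to-trough sizes of 2, 4, 6 and 8 log2 units, although 24, 76, 96 and 100% of them had an unadjusted p under 0.05. With 4000 changed genes it recovered 2.4, 41.4, 83.5 and 93.8% at these sizes, with 91 false calls. The list test gave an exact permutation p of 0.05 or less to 10 of 200 unchanged lists. It did so for 189 of 200 lists that shared a rhythm of 4 log2 units. Residuals were drawn independently for each gene, so the count of 189 does not carry over to lists whose members move together. Lists and figures were handled with the data.table package, version 1.17.8, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.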

Results

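Gene expression was measured in mouse pancreatic islets, the clusters of endocrine cells that secrete insulin and glucagon, every 4 h from ZT0 to ZT20. Each time point was 1 array of RNA pooled from 3 to 5 mice, so there was no replicate at any time point. The share of the 43020 spots that were well above background was 84.4% on the ZT0 array, 66.1% on ZT4, 80.3% on ZT8, 73.2% on ZT12, 70.8% on ZT16 and 75.3% on ZT20. The 75th percentile of the processed signal ran from 543 on the ZT4 array to 2181 on the ZT8 array, and 0 spots were saturated. The ZT0 array had 1743 outlier spots, against 166 to 247 on the others. The number of arrays limits the precision. Across genes, which are not independent replicates, Pearson's r between arrays was highest for ZT16 with ZT20 (0.968) and for ZT4 with ZT12 (0.937) and lowest for ZT12 with ZT20 (0.832).

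The series asked how islet gene expression varies around the day, and the core clock genes were the first comparison. Nr1d1, which encodes the repressor REV-ERB alpha, and Dbp, a clock-controlled transcription factor, had their highest levels in the light phase and their lowest at ZT16 and ZT20. The level of Nr1d1 was 21.6-fold higher at ZT8 than at ZT16, an approximate value because it was not well above background at ZT16 and ZT20. That of Dbp was 7.42-fold higher at ZT4 than at ZT20. Arntl, which encodes the activator BMAL1, was 6.02-fold higher at ZT20 than at ZT4, Cry1, a repressor of BMAL1, 4.04-fold higher at ZT20 than at ZT0, and Nfil3, which opposes DBP, 7.17-fold higher at ZT20 than at ZT8. None of these genes passed the test over all genes.

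The fitted amplitude of Nr1d1 was 4.05 ± 0.93 (SE) log2 units with an acrophase of ZT6.27 and an unadjusted limma p of 0.00984. For Dbp it was 2.73 ± 0.85 at ZT6.03, with an unadjusted limma p of 0.0419. Arntl had 2.23 ± 0.77 at ZT17.3, Cry1 2.09 ± 0.74 at ZT16.0 and Nfil3 2.15 ± 0.89 at ZT19.4, with unadjusted limma p values of 0.0649, 0.0679 and 0.119. Of 24 core clock genes, 21 were measured, without Npas2, Rorb and Bhlhe41. Of these, 0 passed over all genes and 0 passed when adjusted over the list alone (smallest adjusted p 0.207), while 2 had an unadjusted limma p under 0.05. The acrophases of Nr1d1, Dbp, Arntl, Cry1 and Nfil3 stayed within 6 h of these values in the settings compared, the scalings included. Periods of 20 h and 28 h were not part of that comparison. Some other core clock genes moved further, Hlf and Csnk1d in 3 settings each.

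Per2, a repressor, had an amplitude of 3.43 ± 1.47 at ZT16.3 and was not well above background at ZT4. Per1 had 0.88 ± 0.85 at ZT19.5 and Per3, above background on 3 of 6 arrays, had 1.5 ± 1.18 at ZT19.9. Clock gave 2.78 ± 1.27, Rora 2.09 ± 1.27 and Cry2 1.59 ± 0.87, each peaking between ZT17.2 and ZT21.3. Nr1d2 gave 0.70 ± 1.23, Tef 1.07 ± 0.73, Hlf 0.67 ± 1.03, Ciart 1.51 ± 0.99 and Bhlhe40 1.06 ± 0.77. The kinase and ubiquitin ligase genes Csnk1d, Csnk1e and Fbxl21 gave 0.10 ± 0.72, 1.06 ± 0.89 and 1.70 ± 1.01. With scan as a covariate, which draws on the 4 arrays of the shared scan alone, Nr1d1 had 4.97 ± 0.88 and Dbp 2.83 ± 0.70. Nfil3 then had 2.83 ± 0.66, Arntl 1.77 ± 0.81 and Cry1 1.47 ± 0.83. That fit left 1 residual degree of freedom with a prior of 2.51, and its arrays cover only ZT8 to ZT20. Its smaller SEs are therefore no sign of firmer estimates. With the mean of the lymphocyte markers as a covariate, chosen after the data were seen, Dbp had 1.32 ± 1.41 and Nr1d1 had 3.64 ± 1.72.

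**Figure D1:**
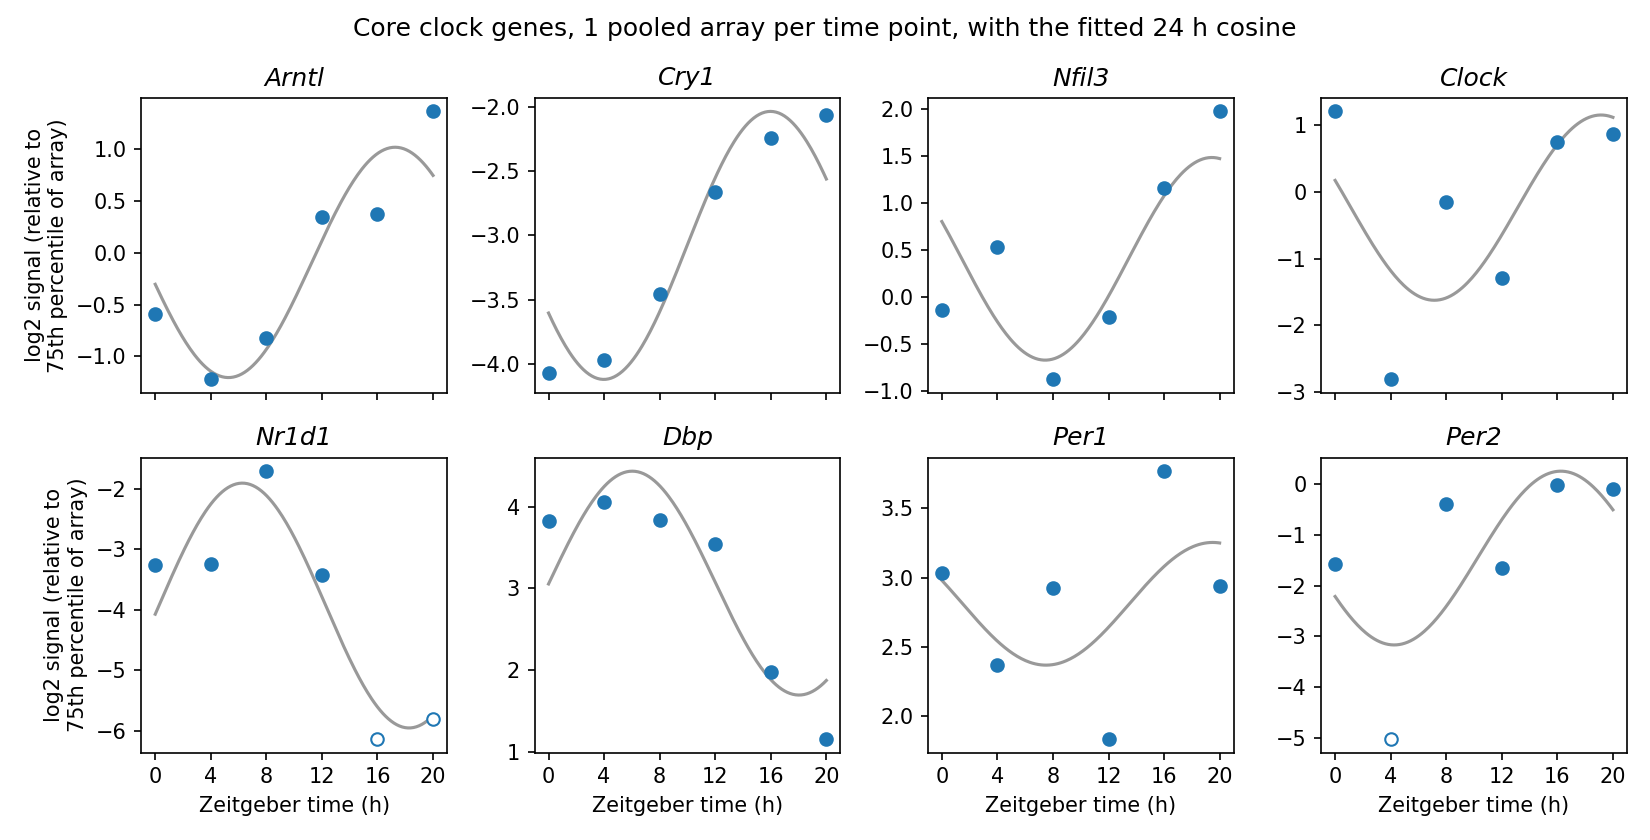
Log2 signal of 8 core clock genes, relative to the 75th percentile of each array, against zeitgeber time in h, with 1 pooled array per point and the fitted 24 h cosine as a line; open circles mark spots not well above background. Nr1d1 and Dbp sit lowest at ZT16 and ZT20, where Arntl, Cry1 and Nfil3 sit highest.

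Across the whole array, the question was which genes followed a 24 h cosine. In the light phase Grap, an adaptor protein of lymphocytes, had an amplitude of 6.71 ± 1.11 (SE) log2 units at ZT7.05, Gimap7, a GTPase of lymphocytes, 5.90 ± 1.36 at ZT6.93, and Slfn2, a regulator of T cell quiescence, 5.45 ± 0.99 at ZT7.13. Siglecg, an inhibitory receptor of B cells, had 3.46 ± 0.79, Pf4, platelet factor 4, had 3.44 ± 0.78 and Map4k2, a kinase, had 3.22 ± 0.70. Cygb, a globin of fibroblasts, had 4.07 ± 0.89, Adamts2, which processes procollagen, 3.19 ± 0.73, Pi16 3.46 ± 0.78 and Rhoj, an endothelial GTPase, 2.98 ± 0.69. In the dark phase the leading genes were Olfr843, an olfactory receptor (3.63 ± 0.66 at ZT23.1), Vmn1r209, a vomeronasal receptor (3.51 ± 0.85), and Catsperd, of the sperm calcium channel (4.27 ± 0.98). Acsm1 and Agmat, which encode mitochondrial enzymes, had 4.78 ± 1.16 and 3.19 ± 0.77. Dll3, a Notch ligand, had 4.86 ± 1.27 at ZT14.5, Atp7a, a copper transporter, 3.26 ± 0.88 at ZT16.0, and Dmbt1, a secreted mucosal glycoprotein, 3.03 ± 0.80. Ccser1 and Grid2ip had 2.68 ± 0.72 and 2.65 ± 0.73.

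None of these 20 genes passed. The limma test called 0 of 24147 genes (smallest adjusted p 0.754), and 968 genes (4.01%) had an unadjusted p under 0.05, where 1207 would be 5% of the genes. An F test without shrinkage and an exact permutation test per gene also called 0, with 682 and 606 genes at an unadjusted p under 0.05. The permutation test cannot give a p below 0.0167, so over this many genes its count of 0 carries little information. The 968 genes had acrophases in the 4 h windows around ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20 in numbers of 120, 208, 533, 38, 40 and 29. Over all genes tested the numbers were 3362, 3490, 4665, 3052, 4462 and 5116. The count of genes with an unadjusted limma p under 0.05 depended on single arrays. It was 4028 without ZT8, 2453 without ZT12, 417 without ZT16 and 348 without ZT20, with 0 called each time. With scan as a covariate it was 441, and with a 12 h harmonic in the fit 136 genes were called.

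Lymphocyte markers differed most between the arrays. Their median deviation from each gene's mean was 0.55 at ZT0, 2.70 at ZT4 (1.94 with quantile normalization), 0.58 at ZT8 (1.06 with quantile normalization), 2.09 at ZT12 (2.08 with quantile normalization), -3.19 at ZT16 and -2.92 at ZT20. The last 4 of these arrays came from the same scan. Ltb (lymphotoxin beta), Cd79b (B cell receptor complex) and Cd3g (T cell receptor complex) had amplitudes of 6.07 ± 1.5, 5.40 ± 1.35 and 6.96 ± 1.76 (SE). Of 12 measured markers, 0 passed over all genes, 9 had an unadjusted limma p under 0.05, and 7 passed when adjusted over the list alone (smallest adjusted p 0.0410). That count was 0 without the ZT0, ZT4, ZT16 or ZT20 array, 0 with scan as a covariate and 0 by the exact permutation test per gene, whose p cannot fall below 0.0167, and this list was singled out after the data were seen. The exact permutation p of the list mean was 0.217 (adjusted 0.784).

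Macrophage, stromal, inflammatory and cell cycle genes also had their lowest medians at ZT16 and ZT20. The macrophage markers were at 1.45 at ZT4, 1.60 at ZT12, -1.60 at ZT16 and -1.36 at ZT20; among them Cd74, the invariant chain, had an amplitude of 3.69 ± 1.06 and Csf1r, the receptor of CSF1, 3.34 ± 1.38. The stromal markers were at 1.0 at ZT0, 0.77 at ZT4 (0.07 with quantile normalization), 0.92 at ZT12 and -1.55 at ZT16, with 4.26 ± 1.33 for Thy1 and 2.01 ± 0.84 for Sparc. Thy1 was highest at ZT4 (7.11) and then ZT12 (6.44), where lymphocyte markers were high, whereas Sparc was highest at ZT0 (6.45). Inflammatory genes stood at 1.58 at ZT12 and -1.78 at ZT16, with 2.80 ± 1.07 for Nfkbia and 1.35 ± 0.88 for Socs3. Cell cycle genes stood at 1.1 at ZT4, 1.22 at ZT12 and -1.17 at ZT20, with 1.09 ± 0.96 for Pcna and 0.57 ± 1.02 for Ccnd1. Each of these medians lay outside the central 95% of random lists, except the stromal one at ZT4. In each of the 4 lists 0 genes passed over all genes and 0 when adjusted over the list alone, and the exact permutation p of the list means was 0.20, 0.367, 0.517 and 0.45.

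The medians of 4 lists of endocrine cell genes ran the other way, lowest at ZT12 and then ZT4. Of their 62 genes, 57 were lowest on 1 of these arrays, but 4 were highest at ZT4. These were Ins1 (8.29 log2 units), Ins2 (8.75), Hnf4a (3.82) and Stx4a (4.47). Apart from Ins2, they were named after their values were seen. Random lists matched on expression to the hormone and granule genes had medians mostly from 0.46 to 1.33 at ZT4. Bright genes thus ran high on that array with this scaling, so the values of Ins1 and Ins2 cannot show a rise in insulin mRNA. The islet transcription factors had medians of 0.96 at ZT0, -1.72 at ZT4, 0.38 at ZT8, -3.02 at ZT12, 1.32 at ZT16 and 1.26 at ZT20. Hormone and granule genes had -0.75 at ZT4, -2.37 at ZT12 and 1.23 at ZT16, glucose sensing and insulin processing genes -1.33, -2.43 and 1.33, and exocytosis genes -0.68, -1.72 and 0.90. With quantile normalization the ZT4 medians of the hormone and exocytosis genes were -1.51 and -1.13. Foxa2 and Insm1, regulators of beta cell identity, had amplitudes of 3.31 ± 1.46 and 2.70 ± 1.18 (SE). The prohormone processing genes Cpe and Pcsk2 had 2.16 ± 0.92 and 1.95 ± 1.02, Rab3a and Napa, of vesicle fusion, 1.85 ± 1.08 and 0.44 ± 0.88, and Iapp and Ins2, which encode amylin and insulin, 1.41 ± 0.73 and 0.53 ± 0.87. In these 4 lists 0 genes passed over all genes and 0 when adjusted over the list alone. The exact permutation p of the list means was 0.45 for transcription factors, 0.383 for hormones, 0.533 for glucose sensing and 0.533 for exocytosis. Lymphocyte markers were highest on the ZT4 and ZT12 arrays, where the medians of these 4 lists were lowest.

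**Figure D2:**
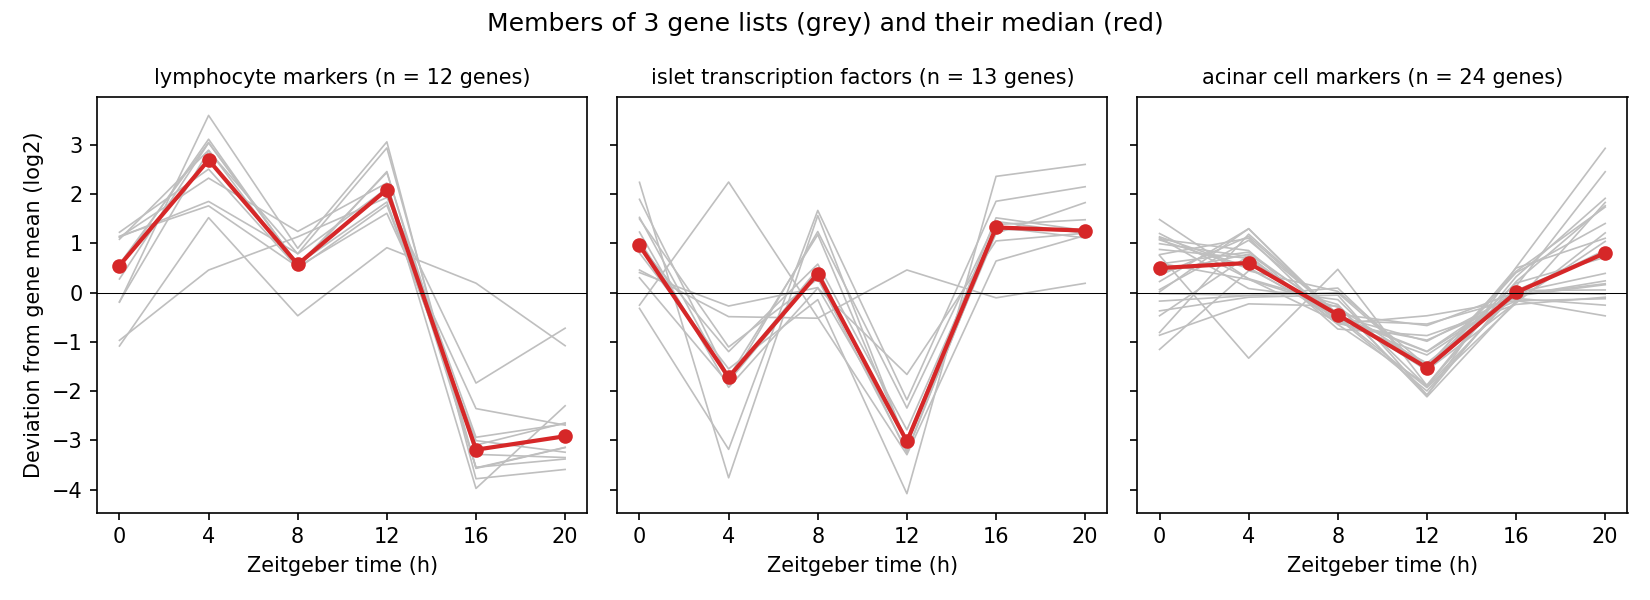
Deviation of each measured member from its own mean over the 6 arrays (grey lines, log2) and the list median (red) against zeitgeber time in h, for lymphocyte markers (12 genes), islet transcription factors (13 genes) and acinar markers (24 genes). Lymphocyte markers lie at 2.70 on ZT4 (1.94 with quantile normalization) and -3.19 on ZT16, and islet transcription factors at -3.02 on ZT12. The acinar median of 0.60 on ZT4 is -0.32 with quantile normalization.

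Unfolded protein response genes, which include the chaperone Hspa5 (1.5 ± 0.74) and the factor Atf4 (1.64 ± 0.80), had medians of -0.79 at ZT4 (-1.32 in the authors' values), -0.57 at ZT12, 0.80 at ZT16 and 0.58 at ZT20, low and high on the same arrays as the endocrine lists (exact permutation p of the list mean 0.367). Sterol and fatty acid synthesis genes, with Acly at 2.16 ± 0.92 and Sqle at 1.28 ± 0.74, ran from -0.43 at ZT4 to 0.51 at ZT20 (exact p 0.183). Acinar markers, the digestive enzyme genes such as Ctrb1 (1.69 ± 0.83) and Try5 (1.90 ± 0.74), were at -1.53 at ZT12 and 0.81 at ZT20 (exact p 0.10), while their 0.60 at ZT4 turned to -0.32 under quantile normalization. Duct markers were at 0.87 at ZT8 and -1.99 at ZT12 (exact p 0.90), with 1.88 ± 1.21 for Tff2 and 0.80 ± 0.66 for Bicc1. Red blood cell markers were at -2.02 at ZT0 and 1.07 at ZT4 (exact p 0.85), with 1.58 ± 0.80 for Hbb-bt and 1.48 ± 0.73 for Hba-a1. Adipocyte markers were at 0.98 at ZT4 and -1.01 at ZT16 (exact p 0.817), with 2.14 ± 0.88 for Fabp4 and 2.08 ± 0.90 for Cidec. Respiratory chain genes were at 0.84 at ZT4, within the central 95% of random lists, and -0.70 at ZT8 (exact p 0.75), which were 0.01 and -0.19 with quantile normalization, with 0.94 ± 0.80 for Atp5b and 1.21 ± 0.96 for Uqcrh.

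Glucocorticoid-responsive genes stayed between -0.29 and 0.22 (exact permutation p 0.417), with metallothioneins Mt1 at 2.05 ± 0.82 and Mt2 at 1.72 ± 1.02. Antioxidant genes stayed between -0.18 and 0.12, or -0.31 and 0.31 with quantile normalization (exact p 0.367), with Sod1 at 0.97 ± 0.90 and Txn1 at 0.96 ± 0.82. Heat shock genes, with Hspa8 at 0.79 ± 0.77 and Hsp90aa1 at 0.45 ± 0.78, had an exact p of 0.70, and immediate early genes, with Nr4a1 at 0.72 ± 0.68 and Btg2 at 0.24 ± 0.71, of 0.60. Endothelial markers, with Egfl7 at 2.30 ± 1.06 and Flt1 at 1.04 ± 0.79, had an exact p of 0.317. Reference genes, with Eef1a1 at 1.28 ± 0.77 and Ppia at 1.65 ± 0.83, had an exact p of 0.40, and their median at ZT4 was 0.61 and turned to -0.13 under quantile normalization. The clock activators had the lowest exact p of the 25 lists: the mean of Arntl, Clock, Nfil3 and Cry1 had an amplitude of 2.16 ± 0.41 at ZT18.1, with an exact p of 0.0667 (adjusted 0.784). The core clock list as a whole had an exact p of 0.70 and the repressor-phase list of 0.867. Opposite phases cancel in such means, as for Arntl (ZT17.3) and Dbp (ZT6.03), or Per2 (ZT16.3) and Nr1d1 (ZT6.27). These 2 p values therefore cannot decide whether single clock genes were rhythmic. In all lists from the glucocorticoid-responsive genes on and the 7 before them, 0 genes passed over all genes. In the same lists 0 passed when adjusted over the list alone, and no list mean passed. A lone list at the smallest exact p of 0.0167 would have an adjusted p of 0.417, so the test of list means could pass only with several lists of small p.

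**Figure D3:**
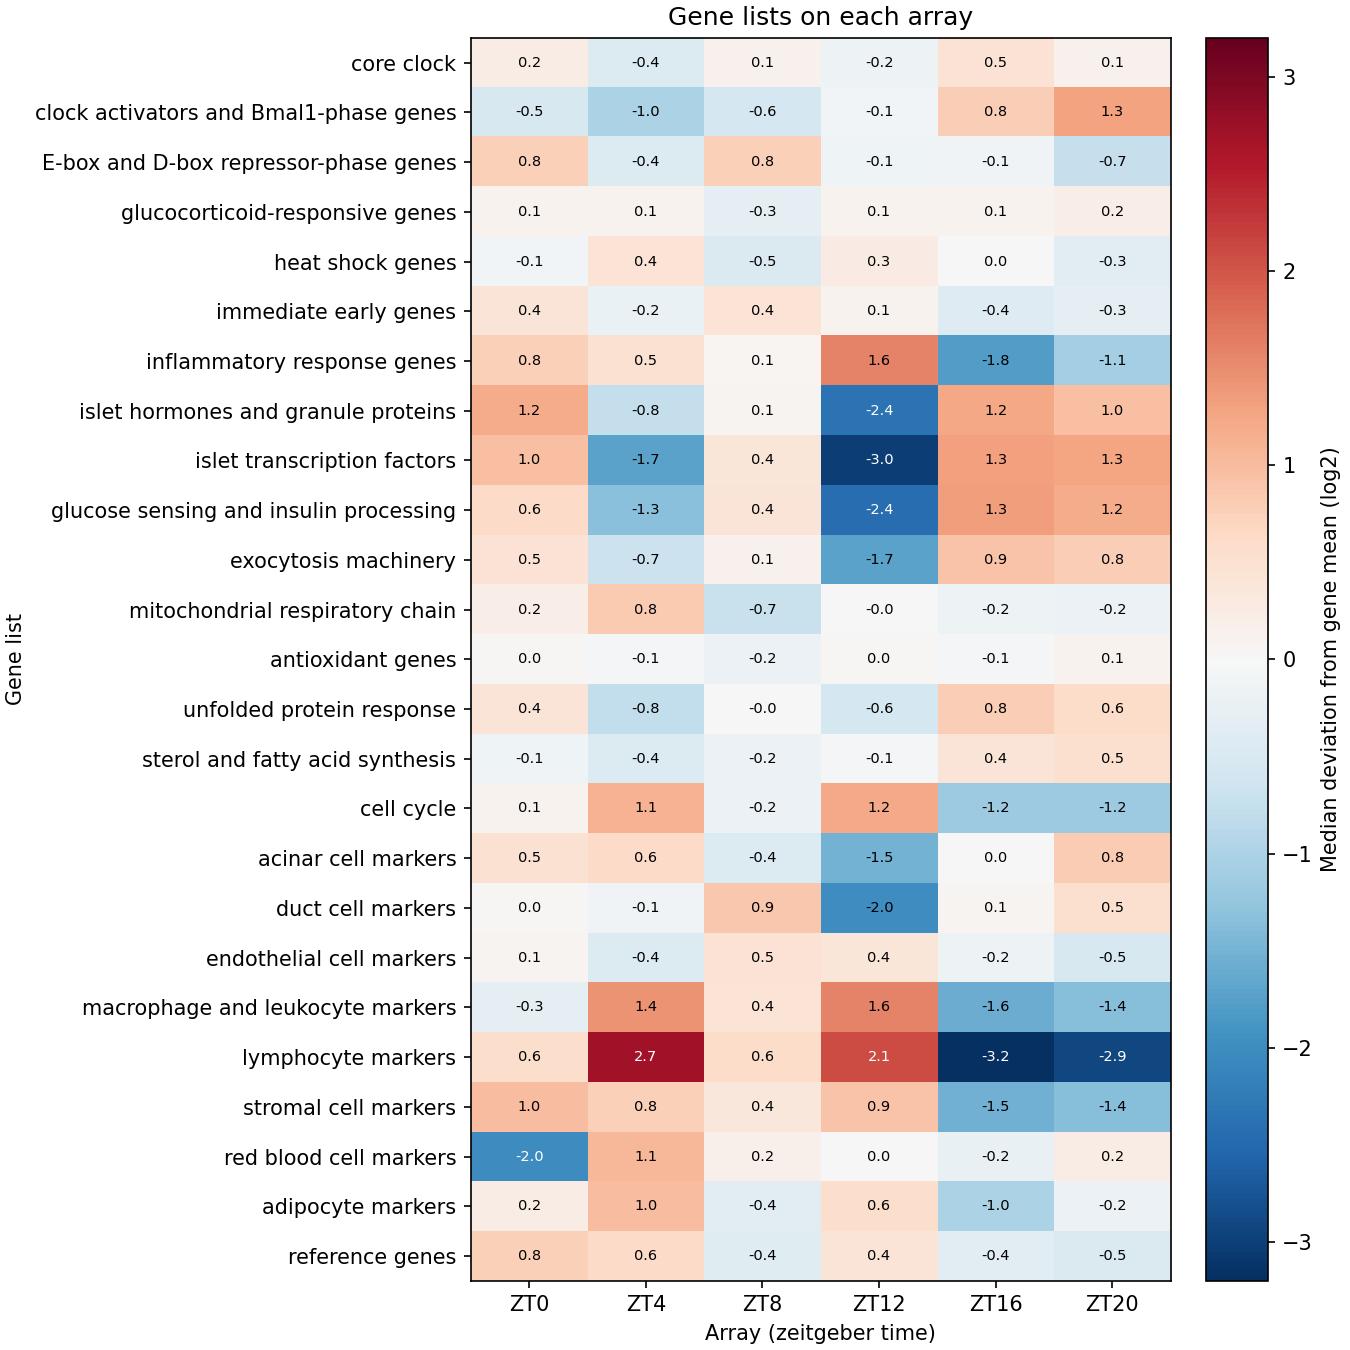
Median deviation (log2, colour and number) of each gene list from the gene means over the 6 arrays, by array on the horizontal axis and list on the vertical axis. Lymphocyte markers reach 2.70 on ZT4 (1.94 with quantile normalization) and -3.19 on ZT16 and islet transcription factors -3.02 on ZT12. The ZT4 values of acinar markers and reference genes turn negative with quantile normalization.

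Single arrays also had genes far from the median of the other 5, given here without a test. Another array could share the level or lie beyond it. Marco was at 6.17 at ZT4 against 4.60 at ZT12 and Dnah2 at 1.44 against 2.12. Angptl4 was at -0.67 at ZT8 against -3.22 at ZT16 and Itih4 at -1.90 against -2.45. On the ZT20 array Alb (albumin) was 1255-fold and Mup19, of the major urinary proteins, 1026-fold above the median of the others; Mup19 belongs to a family of near-identical genes. On the ZT4 array Spink4, of goblet cells, was 748-fold and Fabp2, an intestinal fatty acid binding protein, 252-fold above. On ZT0 the peroxisomal gene Pex6 was 537-fold and the signalling gene Wnt3 296-fold above. On ZT12 Marco, a macrophage scavenger receptor, was 45.5-fold and Dnah2, a ciliary dynein, 30.4-fold above; on ZT8 the class II gene H2-Aa was 22.6-fold and the mast cell protease Mcpt4 17.3-fold above; on ZT16 Krt42 was 27.4-fold and Apol10a 18.4-fold above. The log2 differences furthest below were -5.85 for H2-M5 and -5.18 for Rag2 at ZT0, -5.16 for Reg2 and -5.12 for Lrrn1 at ZT4, and -2.56 for Angptl4 and -2.32 for Itih4 at ZT8. They were -6.76 for Reg2 and -5.98 for Reg3b, both regenerating islet-derived genes, at ZT12, -5.79 for H2-Ob and -5.57 for Cnn1, a smooth muscle calponin, at ZT16, and -5.36 for Grap and -5.24 for Adamdec1 at ZT20.

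Of 18950 genes well above background on all 6 arrays, those at least 2-fold above and below the median of the other 5 numbered 2889 and 3498 on ZT0, 4521 and 3011 on ZT4, 1208 and 330 on ZT8, 3339 and 3435 on ZT12, 1923 and 2328 on ZT16, and 1962 and 2251 on ZT20. With no replicates, these counts do not separate time of day from differences between pools, hybridisations or scans.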

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

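Keeping outlier spots, scan date and the 2 list means as covariates, and leaving out ZT4 and ZT12 together, were alternatives chosen after the results were seen. Of 3761 combinations of a result and an alternative, 3721 kept their side of the threshold or their size. A further 29 moved, 11 passed where they had not, and 0 reversed. Among single genes and lists 3573 of 3597 kept, mostly by not passing again, since 0 genes passed in the main fit. An acrophase shift counted as reversed only for genes that passed there, so no gene's rhythm could reverse. Acrophases moved over 6 h in 3 settings for Hlf and Csnk1d, 2 for Per1, Nr1d2 and Rora, and 1 for Per2 and Fbxl21. Periods of 20 h and 28 h were left out of that count. The count of rhythmic genes was 0 in every setting except the 12 h harmonic, with 136 genes, 115 of them with a peak in the light phase; this fit had 1 residual degree of freedom and a prior of 25.7, and the cause was not tested. The 11 that passed were single genes under that harmonic: Grap, Slfn2, Gimap7, Ltb, Cd3g, Reg2, Reg3b, H2-Ob, Alb, Mup19 and Adamdec1. Core clock genes adjusted over the list alone numbered 0 except without the ZT4 and ZT12 arrays, where 1 (Nr1d1) passed. For lymphocyte markers adjusted over the list alone, 7 by limma, the count was 11 with normexp and the 75th percentile and 11 at a threshold of 0.10. It was 0 with normexp and quantile, no shrinkage, the exact permutation per gene, a 20 h period, scan as a covariate, scan date as a covariate and the lymphocyte mean as a covariate, the last by construction, and 0 to 10 with 1 array left out; except for that mean and the threshold, the cause was not tested. Leaving out 1 array gave 0 rhythmic genes each time, and the count of core clock genes over all genes stayed at 0 in every setting. The count of list means that passed was also 0, with the smallest adjusted p of 0.278 (exact p 0.0111) for the clock activators with a 28 h period. This says little about stability, since in the main fit a lone list at the smallest possible exact p of 0.0167 would have an adjusted p of 0.417; the exact permutation per gene has the same smallest p. Genes with an unadjusted p under 0.05 ran from 246 with a 20 h period to 4028 without ZT8. The median gene shifted by over 0.1 log2 units under quantile normalization at ZT12 (0.10), under the median of detected probes at ZT12 (0.11), and under normexp with the 75th percentile at ZT4 (0.40), ZT0 (-0.21) and ZT8 (-0.19). Signal over background limits genes such as Nr1d1, which was above it on 4 of 6 arrays, and the ZT4 array most, with 66.1% of spots well above background. No paired analysis was possible because each time point was a separate pool of mice.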

Other observations

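The tests of lymphoid, liver and clock patterns and the 4 lists behind them were chosen after the results were seen, except the 3 counts over circular orders of the arrays, which were set beforehand. Hepatocyte genes were high on the ZT20 array alone: of 26 measured, 23 had their highest value there, with a list median of 3.68 against -0.24 to -0.89 on the other arrays. Bhmt and Kng1, of liver metabolism and the kinin system, were 7.83 and 7.89 log2 units above the median of the other arrays, and Alb, an abundant liver transcript outside the list, 10.29. The 3 others were Slc10a1 and Vtn, well above background on all 6 arrays, and C8a, above it on 4; Itih4 was also named in the single-array comparison. Intestinal epithelium genes had a median of 2.81 at ZT4 (2.77 with dim spots at the lowest detected level), with 8 of 13 highest there, among them Guca2a at 7.85 and Lgals4 at 7.05 above the other arrays. Smooth muscle genes had medians of 1.61 at ZT4 and -1.98 at ZT16, with 8 of 10 highest at ZT4. Lymphoid genes outside the marker list had medians of 0.85 at ZT0, 1.89 at ZT4 (1.56 with quantile normalization), 0.64 at ZT8 (0.98 with quantile normalization), 2.14 at ZT12, -2.80 at ZT16 and -2.83 at ZT20.

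Chance could not be excluded for the number of genes with an unadjusted p under 0.05, since 28 of the 60 distinct circular orders of the arrays, the real one included, gave at least as many; the real order gave 968 and the highest other 5924. The same held for the 136 genes called with the 12 h harmonic, reached by 18 of 60 orders, with 3553 as the highest other. By the fit without the harmonic, the real order called 0 genes and 4 of the 60 orders called genes, up to 1099; as seen afterwards, these 4 had ZT4 beside ZT12 and ZT16 beside ZT20, with ZT0 and ZT8 between the pairs. Counts several times the real one under other orders point to a structure of the samples, whose origin was not tested.

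Lymphocyte markers were high on the ZT4 and ZT12 arrays and low on ZT16 and ZT20. An effect shared by the arrays of a scan or slide was argued against. Between ZT12 and the ZT16 and ZT20 arrays of the same scan the markers differed by a median of 5.06 log2 units (quartiles 4.57 and 5.77). This contrast was chosen after the data were seen. These arrays also differed in position on the slide, so an effect of position or hybridisation cannot be told apart from time of day. Lymphoid cells in some pools may account for the pattern: 21 lymphoid genes outside the list differed the same way by a median of 4.98 (quartiles 3.40 and 5.40). The abundant marker Ccl5 was at 7.70 at ZT4 and 0.67 at ZT16. At ZT16, 1 of the 12 markers was above its own mean, Cd3e at 4.64 against 3.97 at ZT8. A 24 h rhythm of the markers cannot be told apart from such cells, since with 1 pool per time point both could give the same course. The exact permutation p of the list mean was 0.217, and this test cannot decide between them at any p. Which tissue such cells came from was not tested.

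Hepatocyte transcripts were high on the ZT20 array. An effect shared by the arrays of a scan or slide was argued against by a median difference of 4.12 (quartiles 2.55 and 6.19) from the ZT16 array. That array came from the same scan but another position on the slide, and an effect of position or hybridisation was not tested. The course of these genes did not have the shape of a 24 h cosine peaking at ZT20. The rise of ZT0 and ZT16 over the 3 opposite arrays was 0.0251 of that of ZT20 (0.12 against 4.72 log2 units). Liver RNA in the ZT20 pool is a candidate explanation, since 92.3% of 26 hepatocyte genes were at least 2-fold above the median of the other 5 arrays there, and Alb reached 6.40 at ZT20 against -5.34 to -3.14 elsewhere. Where liver RNA would have entered the pool was not tested. The hepatocyte list was written after the data were examined, so these outcomes were partly fixed and are weak evidence on each cause.

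The opposite course of Dbp and Nr1d1 against Arntl, Nfil3 and Cry1 may follow the clock of the islet cells or the share of other cells. The difference between the 2 groups of genes was higher at ZT16 and ZT20 than at ZT8 and ZT12 of the same scan. It was higher by 2.74 to 5.53 log2 units, and by 2.17 to 4.81 without Nr1d1. The first range is approximate because Nr1d1 was not well above background at ZT16 and ZT20. These genes were picked from the 21 measured for this course, after the data were seen. That outcome was therefore largely fixed and cannot decide on a scan or slide effect. The SEs of the difference below ignore that choice. The share of lymphoid cells cannot be told apart: the amplitude of that difference was 5.38 ± 1.28 (SE) and, with the lymphocyte mean as a covariate, 4.26 ± 2.73, or 4.73 ± 1.36 and 3.12 ± 2.72 without Nr1d1, so the error with the covariate was too large to decide. Chance could not be excluded over the whole core clock list, whose mean R-squared of 0.48 was reached by 20 of the 60 circular orders, with 0.66 as the highest other. A clock in the islet cells, the biological explanation, stays open.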
